A study of Brassica rapa subsp. chinensis with 6 samples.

How the data were processed

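RNA was sequenced from the aboveground parts of pakchoi (*Brassica rapa* subsp. *chinensis*) at the trifoliate stage, with 3 libraries of the wild type strain 564 and 3 of the chlorotic mutant strain 564Y. The labels call the 3 libraries of a group independent biological replicates. The labels' protocol also speaks of several time points, while the labels themselves give 1 developmental stage. Bowtie2 2.2.3, TopHat2 2.0.12 and DESeq 1.10.1 are named in the submitters' processing notes, with no role given to any of them. The genome build, the annotation and the read counter are not given in the sources used here.

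The data were 1 table of 2958 genes that the authors had already called as different between the strains. Every gene in it had an adjusted p-value of the authors under 0.001 and an absolute log2 ratio of at least 1, so unchanged genes were not analysed here. For each gene the authors deposited the mean read count of each group, treated here as a signal, and the base mean, which is the mean of the read counts after division by a size factor per library. They also deposited the log2 ratio of the mutant base mean to the wild type base mean, per the file headers. The deposited p-value and its adjusted value came from the authors' own test, and 6 p-values were written as 0. A base mean of 0.001 stood for 0 reads in all 148 genes with no read in a group, so no fold is taken from the log2 ratio of those genes. That ratio still entered the ranking of list members for naming and the count at a log2 limit of 2, where it places genes with 0 reads ahead of others whose fold is larger than their bound. All 2958 gene lengths were multiples of 3 and are therefore coding lengths. Product names came from the sequence match in the table. A match was given for 2910 genes, and 1800 had a product description. Of the gene identifiers, 0 were found in the reference gene table, so no coordinates are given. The genome of this species holds many near-identical gene copies, and how reads shared by copies were counted is not given in the sources used here, so values of single members of gene families are uncertain.

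The table gave no values per library, but these could be worked out for most genes. The mean read count times the number of libraries is the sum of whole reads in a group, and the base mean gives the same reads weighted by the size factors, which genes with a single read in a group reveal. Exactly 1 set of whole library counts fitted both values for 2924 genes in the wild type and 2550 in the mutant, and 2550 genes (86.2%) were recovered in both. The remaining 408 genes were the more abundant ones, and 327 of them were higher in the mutant. The recovered genes therefore hold a smaller share of higher genes than the whole table. The size factors were 0.988, 0.983 and 0.961 in the wild type and 1.04, 1.04 and 1.02 in the mutant. The recovered libraries are called A, B and C in each group by size factor, since nothing ties them to the replicate numbers of the labels. Pairs of libraries of a group differed beyond counting noise, with a chi-square per gene of 2.57 to 4.01, so none was treated as a repeat of another library. That they are separate biological samples rests on the labels alone. The recovery was tested on simulated libraries. With randomly drawn size factors, 91.0% of wild type genes and 88.6% of mutant genes had 1 solution, and 0 solutions were wrong. An earlier simulation with round size factors left 1 solution for 72.7% of wild type genes, again with 0 wrong, so the recoverable share depends on the factors.

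The main result was the authors' calls as deposited, because a table of selected genes leaves no background for a test across all genes. For 21 gene lists fixed before the data were examined, members higher and lower in the mutant were compared with the other genes of the table by a two-sided Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method over the 18 lists with a member. This test compares directions within the table and does not show enrichment among all genes. It also treats genes as independent, but neighbouring genes with 1 product mostly moved together (23.1% of 52 pairs opposite, against 48.1% at random). P-values of lists that hold such copies can therefore be too small, also for the groups chosen later. In simulations, a list of 30 genes with 20% higher was called in 95.5% of 200 runs, and unshifted lists in 0.324%. These rates hold for 30 genes whose directions were drawn independently. Most lists had fewer than 30 members, so the 95.5% does not apply to them. Lists were matched by symbol or product words, and 28 memberships rested on a shared word or symbol, as named with the lists concerned. The matching also missed called genes. Examples are the heat shock factor genes AT-HSFA7A and AT-HSFB2A, all higher, and the genes named coronitine insensitive 1 or only LOX, all lower. Counts and tests of lists therefore hold for the matched genes only.

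The quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3 were run on the recovered counts as alternatives chosen after seeing the data. These counts belong to genes selected for the difference between the strains, so the tests are not independent of that selection. In a simulation of 2550 genes, edgeR called genes changed 2-fold in 90 of 100 cases and genes changed 4-fold in 99 of 100. It called unchanged genes in 10 of 2350 cases. The simulated genes were mostly unchanged and shared 1 dispersion. These rates therefore do not describe the test on the selected genes of this table. Standard deviations (SD) are over the 3 recovered libraries of a group. Other values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

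Genes were named by a rule fixed before the data were examined. It took the 5 higher and 5 lower genes with the largest log2 ratio that had a product description and reads in both groups and, where libraries were recovered, did not overlap between the groups. It also took up to 10 members of each chlorophyll list and the 2 members of each other list with the largest log2 ratio. Other genes are named as examples chosen after their values were seen. For a gene with 0 reads in a group, the fold is a lower bound from 3 counts over the group. With 1 to 3 reads the fold has an exact 95% binomial (Clopper-Pearson) interval. Bounds and intervals cover counting error only. Alternatives covered the thresholds, low genes, list membership, test, normalization and left-out libraries.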

Results

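The transcriptome of a chlorotic pakchoi mutant, strain 564Y, was compared with that of its wild type, strain 564, in the aboveground parts of plants at the trifoliate stage. Each strain had 3 libraries. The table analysed lists 2958 genes that the authors called as different. Their mean read counts sum to 1348884 reads per library in the wild type and 1677855 in the mutant. These sums cover called genes only and are not library depths, which are not given in the sources used here. Normalised read counts below are the authors' base means, and folds are ratios of these means.

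The comparison asked which genes differ between a plant with chlorosis and its wild type. All 3 called genes matched to chlorophyll biosynthesis were lower in the mutant, and genes of the glucosinolate, flavonoid and defence lists were mostly lower. In the authors' deposited table, 1766 genes were higher in the mutant and 1192 were lower. Among genes with reads in both groups, the median absolute log2 ratio in the authors' deposited table was 1.70 for the 1681 higher genes (quartiles 1.28 and 2.52) and 1.54 for the 1129 lower genes (quartiles 1.22 and 2.14). A further 85 genes had 0 reads in the wild type and 63 had 0 reads in the mutant. In the 2550 genes with recovered libraries, the 3 mutant libraries did not overlap the 3 wild type libraries in 2550 genes, where chance gives 10%, but these genes had been selected for the difference. The median coefficient of variation between libraries was 12.3% in the wild type and 12.1% in the mutant among recovered genes with a base mean of at least 20.

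Chlorophyll biosynthesis had 3 called members, and all 3 fell. Protochlorophyllide reductase (Bra022628), which makes chlorophyllide in the light, fell 5.29-fold from 334.1 ± 22.4 to 63.1 ± 3.68 normalised reads (SD, n = 3 recovered libraries each). Glutamyl-tRNA reductase (Bra031690), the first committed enzyme of tetrapyrrole synthesis, fell 3.85-fold from 406.2 ± 62.0 to 105.6 ± 3.61 (SD, n = 3 recovered libraries each). The magnesium chelatase subunit CHLI1 (Bra012595), which takes part in inserting magnesium into protoporphyrin, fell 3.70-fold, with authors' means of 4684 and 1267. The log2 changes fitted by edgeR's quasi-likelihood test were -2.40 (SE 0.16, Benjamini-Hochberg adjusted p = 4.6e-11) for protochlorophyllide reductase and -1.94 (SE 0.15, adjusted p = 6.34e-10) for glutamyl-tRNA reductase. Each SE was derived from the log2 change and its F statistic. All 2550 recovered genes had been selected for the difference and all passed 0.05 in this test. These p-values are therefore no independent evidence for either gene. With all 3 members lower, the two-sided Fisher's exact test gave p = 0.0653 (adjusted p = 0.196), the smallest it can give for 3 lower members, so the list was too small to be tested in this direction. The lists of chlorophyll breakdown, light-harvesting antenna and carotenoid biosynthesis had 0 called members each, which means that no matched gene passed the authors' thresholds. Only 1800 of the 2958 genes had a product description, so called genes of these pathways can have gone unmatched.

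**Figure D1:**
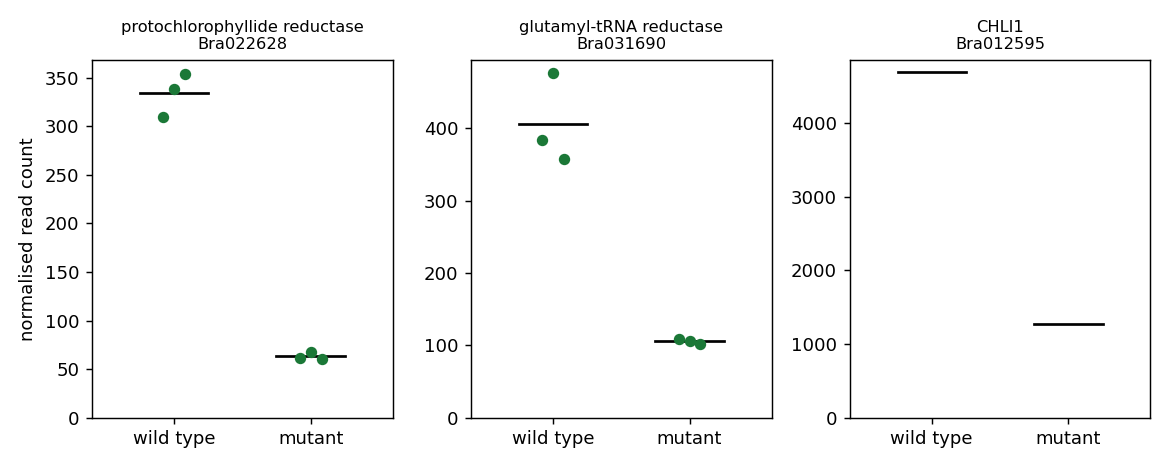
Normalised read count (vertical axis, linear, starting at 0) of the 3 called chlorophyll biosynthesis genes in wild type and mutant; points are recovered libraries and bars are the authors' base means. Protochlorophyllide reductase fell from 334.1 to 63.1 and glutamyl-tRNA reductase from 406.2 to 105.6 with no overlap of libraries, and CHLI1, whose libraries were not recovered, is drawn as its means of 4684 and 1267.

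Few called genes were matched to the photosynthetic machinery itself. Of 5 genes matched to photosystems and electron transport, 4 were higher and 1 was lower (adjusted p = 0.841, Fisher's exact test). The lower gene was photosystem I subunit G, PSAG (Bra038011), at 1589 ± 465 in the wild type and 602.6 ± 102 in the mutant (SD, n = 3 recovered libraries each). The 4 higher genes were named plastocyanin-like, a family of copper-binding cell surface proteins rather than the thylakoid carrier, among them Bra003027 (11.4-fold) and Bra005941 (16.7-fold, interval 5.52 to 85.0). In carbon fixation, 1 gene was higher and 3 were lower (adjusted p = 0.506, Fisher's exact test). A ribulose bisphosphate carboxylase gene (Bra034027) fell 18.6-fold (interval 6.06 to 93.6) at a low level, 18.1 against 0.971 normalised reads, and a transketolase-like gene (Bra003426) rose 9.14-fold to 15.4. The third lower member, CES101, is a receptor kinase matched by its name. The plastid gene expression list had 4 higher and 2 lower members (adjusted p = 1, Fisher's exact test). In it, 4 members were purple acid phosphatases that share a symbol with plastid proteins, including both lower members. These were the PAP29 genes Bra038610, at 22.5 normalised reads against 0 reads in the mutant and at least 23.3-fold lower, and Bra038611, which was 3.80-fold lower. The other 2 members were CGA1 (Bra026461), a GATA factor of chloroplast development, 2.18-fold higher, and the import protein Toc64-III (Bra018737), 2.11-fold higher. Of the 3 genes matched to cytosolic ribosomal proteins, 0 were higher (adjusted p = 0.196, Fisher's exact test, likewise too few to pass), and the only ribosomal protein among them was 60S L4/L1 (Bra001302), which fell 2.82-fold, since RPP1 and RPS2 are resistance proteins.

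Genes of glucosinolates, the sulfur-rich defence compounds of the cabbage family, were mostly lower. Of 23 members, 18 were lower and 5 higher, a share of 21.7% higher against 60% among the other genes (two-sided Fisher's exact test, adjusted p = 0.00306). The lower members included all 5 cytochrome P450 genes of the core pathway in the table, such as CYP83B1 (Bra034941), with authors' means of 9732 and 3681, and 7 of 8 myrosinases, the enzymes that split glucosinolates. AOP1 (Bra000848) fell 205-fold, from 262.1 to 1.28 normalised reads, while the myrosinase Bra023838 rose 43.8-fold (interval 11.7 to 364). Phenylpropanoid and flavonoid genes had 12 lower and 3 higher members, 20% higher against 59.9% (adjusted p = 0.0148, Fisher's exact test). All 4 chalcone synthase genes of the list, which open the flavonoid pathway, and both chalcone isomerases were lower. Flavonoid 3'-hydroxylase (Bra009312) fell 8.41-fold from 1086 ± 64.1 to 129.2 ± 19.4 (SD, n = 3 recovered libraries each), and a 4-coumarate CoA ligase gene (Bra016466) fell 14.5-fold, while the other 2 ligase genes of the list (Bra012232 and Bra025823) rose. Among genes with recovered libraries alone, 29.4% of 17 glucosinolate genes and 23.1% of 13 phenylpropanoid genes were higher, and with these fewer genes neither list passed the test (adjusted p = 0.168 for both, Fisher's exact test). At an absolute log2 ratio of at least 2, 40% of 10 and 33.3% of 3 genes were higher, again without passing (adjusted p = 0.387 and 0.573, Fisher's exact test).

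Defence genes were also mostly lower, with 36 of 54 members lower, 33.3% higher against 60.2% among the other genes (two-sided Fisher's exact test, adjusted p = 0.00201). WRKY transcription factors, many of which act in immune responses, made up 19 members, of which 14 were lower. WRKY53 (Bra013732) fell from 1609 ± 73.4 to 358.5 ± 10.6 (SD, n = 3 recovered libraries each). Pathogenesis related protein 1 (Bra013124) fell 70.3-fold. Genes named for disease resistance went both ways. Bra027791 rose 160-fold from 4.42 to 707.8 normalised reads, and Bra039560 had 0 reads in the wild type and was at least 13.2-fold higher, while the RPP1-like gene Bra019410 fell 9.80-fold. This call ended at an absolute log2 ratio of at least 2 (adjusted p = 0.165, Fisher's exact test). On recovered genes (adjusted p = 0.0254) it also ended without wild type library A (0.242), mutant library B (0.239) or mutant library C (0.0792), by the same exact test.

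**Figure D2:**
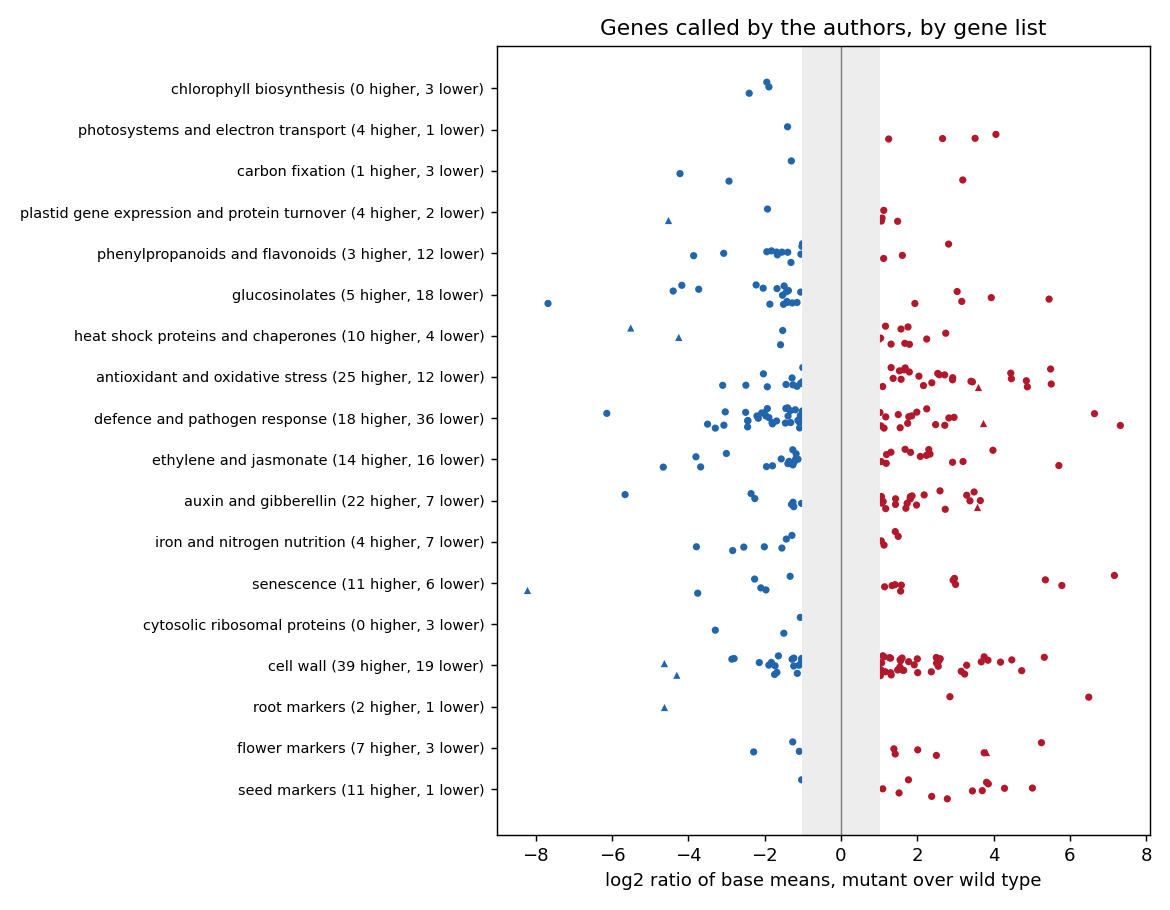
Log2 ratio of base means, mutant over wild type (horizontal axis), of every called gene in each of the 18 lists with a member; each point is a gene, triangles are genes with 0 reads in a group drawn at their bound, and the grey band from -1 to 1 holds no gene by selection. Glucosinolates (18 of 23 lower), phenylpropanoids (12 of 15 lower) and defence (36 of 54 lower) lie mostly to the left.

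The hormone lists, as matched, did not pass the test of direction. Ethylene and jasmonate genes had 14 higher and 16 lower members (adjusted p = 0.379, Fisher's exact test), one of which, a rectifying potassium channel, was matched by a word in its name. The 4 genes named JAZ, repressors of jasmonate signalling, fell, while another member of that family, TIFY 7 (Bra007937), rose. The lipoxygenase LOX2 (Bra022535), an enzyme of jasmonate synthesis, fell 12.8-fold from 3747 to 293.0 normalised reads. An ethylene-insensitive3 gene (Bra023927) rose 52.4-fold to 622.3, and an ethylene responsive element binding factor (Bra038087) fell 25.2-fold. Auxin and gibberellin genes had 22 higher and 7 lower members (adjusted p = 0.224, Fisher's exact test). SAUR68 (Bra032317) had 0 reads in the wild type and was at least 11.9-fold higher, and the auxin-responsive gene Bra018403 fell 50.4-fold (interval 13.5 to 421). Gibberellin 20-oxidase GA20OX2 (Bra022565) rose 11.2-fold.

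The stress and nutrition lists did not pass the test of direction either. Antioxidant genes had 25 higher and 12 lower members (adjusted p = 0.59, Fisher's exact test), 3 of them matched only by an annotated activity. The list mixed groups that went opposite ways. Of its 37 members, 22 were class III peroxidases, which act in the cell wall, and 21 of these were higher. The count of the whole list therefore does not describe its remaining members. Peroxidase 64 (Bra001986) rose 45.6-fold from 19.1 to 870.8 normalised reads and peroxidase ATP13a (Bra023639) was at least 12-fold higher than 0 reads, while 8 of 10 glutathione S-transferases were lower. Heat shock genes had 10 higher and 4 lower members (adjusted p = 0.59, Fisher's exact test). HSP101 (Bra015922) rose 4.75-fold, and the genes Bra014918 and Bra003501 had 0 reads in the mutant, at least 45.5-fold and 19-fold lower. Iron and nitrogen genes had 4 higher and 7 lower members (adjusted p = 0.296, Fisher's exact test). The high-affinity nitrate transporter Bra018655 fell 13.8-fold and the nitrate transporter Bra019744 fell 7.15-fold, the chloroplast iron store ferritin-1 (Bra005677) fell 2.44-fold, and nitrate reductase (Bra003670) rose 2.19-fold. Genes of the senescence list had 11 higher and 6 lower members (adjusted p = 0.907, Fisher's exact test). Of these 17 members, 11 were NAC transcription factors, 7 higher and 4 lower. The count therefore mostly describes that family. A senescence-associated cysteine protease (Bra038206) rose 144-fold (interval 25.2 to 5670), and the NAC factor anac017 (Bra034436) had 291.1 normalised reads in the wild type and 0 reads in the mutant, at least 301-fold lower.

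Cell wall genes had 39 higher and 19 lower members, 67.2% higher against 59.6% (adjusted p = 0.504, Fisher's exact test). Within the list, 12 of 14 xyloglucan endotransglucosylases, which remodel the wall during growth, were higher, as were 6 of 7 pectate lyases. A cellulose synthase catalytic subunit gene (Bra006407) rose 2.46-fold, while 4 cellulose synthase-like genes, ATCSLG3 (Bra019253), ATCSLG2 (Bra013750), ATCSLA15 (Bra008638) and ATCSLA10 (Bra012416), fell. A polygalacturonase (Bra014620) and the receptor kinase PERK13 (Bra016218) had 0 reads in the mutant, at least 19.7-fold and 24.7-fold lower. The families named within lists were picked after their values were seen and were not tested.

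Markers of other organs were counted because the share of organs in a sample can differ. Root markers had 2 higher members and 1 lower (adjusted p = 1, Fisher's exact test): MLP34 (Bra003939) rose 90.1-fold (interval 16.1 to 3655) to 31.3 normalised reads, RHD2 (Bra029194) rose 7.24-fold to 56.7, and PERK13 fell as given above. Flower markers had 7 higher and 3 lower members (adjusted p = 0.899, Fisher's exact test), among them the AGL8 homolog Bra012997, at least 13.9-fold higher than 0 reads, and the AGL9 homolog Bra010955, 38.2-fold higher (interval 10.1 to 317). In that list 3 members were not floral genes, namely both EXPA9 expansins and stress enhanced protein 2. Seed markers had 11 higher and 1 lower (adjusted p = 0.155, Fisher's exact test), but 10 of the 12 belonged to the lipid transfer protein family, such as Bra037222 (32.4-fold higher) and Bra023816 (19.5-fold higher).

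The largest changes came close to presence in 1 strain and absence in the other. On the mutant side, Bra008053 averaged 3923 normalised reads against 0.347 in the wild type, an 11310-fold difference (interval 2064 to 454233). Its description reads only ATP binding, protein binding and transmembrane receptor, which does not name the protein. The homeobox gene Athb-3 (Bra018154) was 503-fold higher (interval 89.3 to 19772) and the oxidoreductase gene Bra028286 138-fold higher (interval 46.7 to 668). On the wild type side, a glucosyl transferase gene (Bra023863) averaged 2720 normalised reads against 0.321, an 8482-fold difference (interval 1515 to 333547). MRH5/SHV3 (Bra004101) was 1161-fold lower in the mutant, a 2-isopropylmalate synthase gene (Bra013007) 704-fold lower (interval 194 to 5794), wall-associated kinase 2 (Bra025883) 268-fold lower and the phosphatase-associated gene Bra033843 239-fold lower (interval 66.6 to 2004).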

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

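No paired analysis was possible because the recovered libraries carry no replicate number. The planned settings that need values per replicate (replicate block, without each replicate, pseudocounts) were therefore not run, and the settings on recovered counts, left-out recovered libraries, name matches, recovered genes alone and genes at or under 3 reads were chosen after seeing the data. FDR limits of 0.01 and 0.001 and a log2 limit of 1 removed no gene, since the table already met them, and say nothing about stability. At an absolute log2 ratio of at least 2, 1119 genes were left, 727 higher and 392 lower, genes with 0 reads included. On the 2550 recovered genes at the authors' limits edgeR called 2546 (1435 higher and 1111 lower) and DESeq2 2518. Scaling by TMM over these selected genes moved the median log2 by -0.35 and changed the sign of 0 genes. With it edgeR called 1035 higher against 1111 lower at those limits, to be set beside the 1435 and 1111 without it. TMM is of little weight here because it takes called genes as the reference. Leaving out 1 recovered library gave 2342 to 2450 genes. Of 406 values of named genes on recovered counts, 0 changed direction. Their side of the 0.05 threshold says nothing about stability, because nearly all of these selected genes pass it under every setting.

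Of 251 recomputed list values, 214 kept their direction and call. At a log2 limit of 2 the share of higher members was 33.3% for phenylpropanoids, 40% for glucosinolates and 38.1% for defence, none past the threshold. The direction relative to the other genes turned for plastid genes (0%), heat shock (50%), ethylene and jasmonate (66.7%) and senescence (60%), with fewer genes in each. At that limit 727 genes were higher and 392 lower, so ethylene and jasmonate and senescence lay close to the share of all genes. Recovered genes alone, with all libraries, gave 23.1% for phenylpropanoids and 29.4% for glucosinolates, no longer past the threshold. They also turned plastid genes (33.3%) and cell wall (56.1%), because abundant members are missing there. Of all recovered genes 1439 were higher and 1111 lower, so cell wall was level with the other genes rather than clearly turned. Leaving out 1 library on the same genes gave 18.2% to 25% for phenylpropanoids, 29.4% in each case for glucosinolates, 33.3% to 38.6% for defence, 0% to 33.3% for plastid genes and 52.6% to 61.1% for cell wall. Defence lost its call without wild type library A, mutant library B or mutant library C. Flower markers turned without the lowest 25% of genes by mean (57.1%), where root markers had no member, and photosystem genes turned without shared names (0%, from 1 gene). The cause was not tested further.

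The median absolute log2 ratio of higher genes was 1.49 without the lowest 25% of genes, 1.76 with 0-read genes at their bound, 1.66 without genes at or under 3 reads, 1.78 with edgeR and 1.76 to 1.81 without 1 library. For lower genes it was 1.42, 1.59 with genes at their bound, 1.57 with edgeR and 1.55 to 1.62 without 1 library. Only 1 of the 10 splits of the 6 libraries, the real one, gave 2550 genes, and the highest of the others gave 0. So few splits cannot give a share under 0.05, and the genes were selected for the real split.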

Other observations

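All tests in this part were chosen after the results were seen, and its 8 gene groups were drawn up after searching the product names of the table, so their adjusted p-values do not cover that search. The adjustment over the 8 groups also includes light and shade signalling, which was assembled from genes already seen to be higher. Its small p-value makes the adjusted p-values printed here for other groups smaller. Class III peroxidases, which act in the cell wall, were higher in 21 of 22 cases (two-sided Fisher's exact test, adjusted p = 0.00104), among them peroxidase 21 (Bra023099), with authors' means of 2476 and 10208. All 22 belong to the antioxidant list, which did not pass the test. Lipid transfer proteins were higher in 12 of 13 cases (adjusted p = 0.04, Fisher's exact test), but 10 of them are also in the seed marker list, which did not pass with 11 of 12 higher (adjusted p = 0.155, Fisher's exact test). Receptor-like and wall-associated kinases matched to their group were lower in 23 of 35 cases (adjusted p = 0.00743, Fisher's exact test). These include neighbouring copies, such as the wall-associated kinase 2 genes Bra025882, Bra025883 and Bra025886, which all fell. Other called genes with receptor kinase names were left out of the group, among them Bra030161, which rose, and Bra030167, which fell. Wax and fatty acid elongation genes had 7 higher members and 1 lower (adjusted p = 0.176, Fisher's exact test). CER1 (Bra032670), an enzyme of wax alkane synthesis, rose 4.41-fold to 6075 normalised reads, and KCS9 (Bra037304) rose 11.2-fold from a lower level. The 7 genes matched as tubulins by symbol or product were higher, which did not pass the test (adjusted p = 0.0743, Fisher's exact test).

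A set of 239 genes had 3 or fewer reads in 1 strain, 148 in the wild type and 91 in the mutant. Chance zeros at low depth are argued against for 37 of them, which averaged over 100 reads per library in the other strain. A candidate explanation is a sequence or copy difference between the strains that spans neighbouring genes, taking gene numbers as their order. Among genes near 0 in the mutant, 17 had another within 10 gene numbers, against a median of 4 in 10000 random picks of lower genes (one-sided permutation test, p = 0.001), while for the wild type the values were 20 and 12 (one-sided permutation test, p = 0.081), which leaves it open there. Genes at least 4-fold lower with over 3 reads in both groups had 65 with a neighbour against a median of 53 (one-sided permutation test, p = 0.09), and the higher ones 166 against 169 (one-sided permutation test, p = 0.59). Shared regulation of neighbouring genes is not excluded by these values, and poor mapping of 1 strain's reads was not tested.

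Light and shade signalling genes in the table were all higher, 23 of 23, but the group was assembled from genes already seen to be higher, so this count is no evidence of a direction. It held both HFR1 genes, regulators of far-red responses (Bra032610, 17.3-fold, and Bra033315, 2.56-fold), phytochrome A (Bra020013, 2.74-fold) and both flowering locus T genes, such as Bra004117 (7.57-fold). Whether the libraries of the strains were taken at another time of day stays open. The table held 6 circadian clock genes, all higher (adjusted p = 0.116, Fisher's exact test), such as pseudo-response regulator 1b (Bra035933, 2.47-fold), but this group was drawn up from names already seen in the table, so its presence does not test that explanation. A change in light signalling in the mutant strain stays open as an untested biological hypothesis.

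The higher peroxidases could come from root tissue in the mutant libraries, although the labels give aboveground parts, a sampling that would leave roots out. Of 6 root-preferred genes, which include the 3 fixed root markers, 4 were lower in the mutant, such as NRT2.5 (Bra016747, 5.84-fold), while MLP34 (90.1-fold) and RHD2 were higher. On the fixed markers alone 2 of 3 were higher. With 6 genes going both ways this cannot be told apart from chance (exact binomial test, one-sided for lower, p = 0.344). The test took higher and lower as equally likely, although more genes of the table were higher. The nitrate transporters among the 6 genes could also respond to nutrition. A strain effect on peroxidases in the shoot was not tested.

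Neighbouring genes with the same product mostly moved together. Of 52 such pairs within 10 gene numbers, 12 moved in opposite directions (23.1%), against 48.1% if directions were drawn at random, though pairs that share a gene are not independent. Such neighbours can be near-identical copies. How reads shared by copies were counted is not given, so a part played by the counting is not excluded. The methylthioalkylmalate synthase genes Bra013009, which fell 21.1-fold, and Bra013011, which rose 8.26-fold, were one of the opposite pairs.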
